A study of Mus musculus with 2 samples.

How the data were processed

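Natural killer (NK) cells were taken from subcutaneous tumors of mice given RMA-S cells, a mouse lymphoma line with low surface MHC class I. The tumors were collected 2 weeks after injection, per the labels. The cells had been sorted as CD3ε-negative and NK1.1-positive and made into 10x Chromium 3′ libraries, in which a tag near the 3′ end of each transcript is read with a unique molecular identifier (UMI). There was 1 library from mice lacking Hif1a in NK cells (the KO library) and 1 from wild-type mice (the WT library). The labels do not say how many mice or tumors went into either library, nor give dates or sort batches.

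The deposited tables held whole-number UMI counts per gene and barcode, not normalized, per the labels and as seen in the values. Cell Ranger 2.0.2, Seurat and the mm10 build are named without a role in the submitters' processing notes. The gene annotation, the rule for calling cells and any removal of doublets are not given in the sources used here. Both tables listed 27998 gene symbols. The KO table held 3110 barcodes and 13407906 UMIs, with 1464 to 29202 UMIs per barcode. The WT table held 3574 barcodes and 19553440 UMIs, with 2364 to 52557 per barcode. The lowest barcode of the WT library was thus deeper than that of the KO library, and both ends of that range depend on how barcodes had been called.

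From these counts, barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left 3067 KO and 3555 WT cells. Both libraries were clustered together with scanpy 1.11.5 (counts per 10000, log1p, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8 with leidenalg 0.10.2), with no integration. A cluster received a class name from marker lists set before the data were examined. Its top 10 genes by fold decided the name where at least 3 were markers of 1 class, otherwise the class with the highest mean share of cells carrying its markers did, provided no other class led. Clusters under 20 cells stayed unnamed. NK-like cells were clustered again at resolution 0.6. Scrublet marked 2 of 6622 cells (0.0302%), so its doublet calls were not relied on. Why it marked so few was not tested. Doublets were therefore kept, and an alternative left out the 3% of cells with the highest scores in each library.

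UMIs were summed over the NK-like cells of each library and scaled to CPM, that is per 1e6 UMIs of those sums. The ratio was log2 of KO over WT with 1 CPM added to both. With 1 library per genotype no test was made, and no p-value or standard error is given. Exact 95% Poisson intervals of sums, exact conditional binomial intervals of ratios and exact binomial (Clopper-Pearson) intervals of shares cover counting error only, not differences between mice, tumors or preparations. Intervals of sums and ratios take UMIs as independent, so they are too narrow where few cells hold most UMIs of a gene. Ratio intervals were computed without the added CPM, so for sparse genes they lie further from 0 than the ratio. For each gene list, the median log2 ratio over members with at least 50 UMIs was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called apart at or under percentile 2.5 or at or over percentile 97.5, as a description of these libraries. List members were also counted at 1.5-fold. The lists, markers, rules and most alternatives were set before the data were examined. Those chosen afterwards are named as such in the closing section.

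Genes were named by a rule of size. It took Hif1a, then the 12 highest and 12 lowest log2 ratios among genes with at least 200 UMIs over both libraries whose ratio went the same way in each NK-like sub-cluster with at least 100 cells of both libraries. Xist, Tsix and Y-linked, mitochondrial, ribosomal protein, hemoglobin and antigen receptor genes and unnamed gene models were left out of that part. It then took up to 4 members of each list with at least 100 UMIs and the largest absolute ratio. This gave 120 genes, of which the text describes a part. Genes named outside the rule are said to have been chosen after their values were seen. To compare shares of cells, each cell was thinned to 2500 UMIs, the 10th percentile of NK-like cells rounded down, which left out 406 KO and 90 WT NK-like cells as too shallow.

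Gene positions come from GENCODE M21 on GRCm38, the assembly also called mm10, and all 120 named symbols had 1 record there. The submitters' annotation may differ from it. Granzyme genes Gzmc to Gzmg, the Klra family and the Bcl2a1 copies are related in sequence within each family, and Gapdh has many pseudogenes. How far their members differ was not examined, so their UMIs are uncertain where the counting could split them. The summing, intervals and list percentiles were tested on simulated counts drawn from the means of this comparison over 7997 genes, 200 of them changed. The 95% interval covered the true ratio for 95.3% of the 7797 unchanged genes, the direction was recovered for 100% of genes changed 2-fold or 4-fold either way, and 5.5% of 200 unchanged lists were called apart. These counts were independent Poisson draws per gene, so coverage near 95% was built in, and the unchanged lists were random genes. The simulation therefore checks the computation only. It has neither UMIs gathered in few cells nor genes that move together. Alternatives covered the cells used, scaling, cell weighting, doublets, cycling cells, sub-cluster composition, mitochondrial limit, count minimum, prior and clustering. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.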

Results

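Single-cell transcriptomes of tumor-infiltrating NK cells were compared between a KO library, from mice lacking the hypoxia-inducible transcription factor subunit Hif1a in NK cells, and a WT library. The comparison asks how loss of Hif1a relates to gene expression of NK cells in RMA-S tumors. Each genotype had 1 library, so no difference below has a replicate check, and each describes the 2 libraries rather than the genotypes. After filtering, the KO library had 3067 cells and the WT library 3555. NK-like cells had a median of 3744 UMIs and 1502 genes in the KO library, and 4420.5 UMIs and 1627 genes in the WT library. Their sums were 12354447 and 18134676 UMIs. Xist was present at 629 CPM in the KO and 574 CPM in the WT library, and the Y-linked genes summed to at most 3 UMIs per library.

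The targeted gene did not separate the libraries. Hif1a (chromosome 12, 73901375 to 73947530, plus strand) had 754 UMIs in KO NK-like cells, or 61.0 CPM, and 1064 UMIs in WT NK-like cells, or 58.7 CPM. The log2 ratio was 0.056 (95% counting interval -0.080 to 0.19). After thinning, 12.4% of KO and 12.9% of WT NK-like cells carried a Hif1a UMI, with intervals of 11.2% to 13.8% and 11.8% to 14.1%. The tags of a 3′ library can lie outside the deleted part of the gene, which the labels do not give, so this value checks nothing about the deletion.

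Both libraries consisted largely of NK-like cells, as the sort would give. The NK-like share was 94.8% in the KO library (exact 95% interval 93.9% to 95.5%) and 93.6% in the WT library (92.7% to 94.3%). A T-like cluster led by Cd3d, Cd3g, Cd3e and Bcl11b held 69 KO and 108 WT cells. A cluster led by Tmem176b, Tmem176a, Cd74, Il7r and Rora held 85 KO and 115 WT cells and stayed unnamed. Different clusters held most of the NK-like class in the 2 libraries. Among NK-like sub-clusters, number 1, led by Nr4a1, Nfkbiz, Nfkbid and Csrnp1, held 1593 of 2907 KO cells and 158 of 3326 WT cells. Number 2, led by Ndrg1 and Emb, held 390 KO and 993 WT cells, and number 0, led by Klrg1 and Gpx8, held 45 and 503. Such clusters may be libraries rather than cell types, so their sizes are given only as the make-up behind the values that follow. They were drawn from the same counts, and number 1 was led by genes compared below. Ratios of such genes within sub-clusters, or under the WT make-up, can shrink in either of 2 cases. Cell types may differ in number, or the same cells may have changed state. Those values cannot tell these cases apart.

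Among 7997 genes with at least 200 UMIs, 127 were at least 2-fold higher and 76 at least 2-fold lower in the KO library. Of these, 95 and 40 went the same way in each of the 4 sub-clusters compared. The highest ratios by the size rule included the NF-kB regulators Nfkbid and Nfkbiz, the orphan nuclear receptor gene Nr4a1, the angiogenic factor gene Vegfa and the stress-response gene Gadd45b. Nr4a1 (chromosome 15, 101254269 to 101274795) stood at 1080 CPM in the KO and 226 CPM in the WT library, a log2 ratio of 2.25 (2.21 to 2.31). Nfkbid stood at 248 and 49.3 CPM, Vegfa at 299 and 60.2 CPM, and Gadd45b at 723 and 161 CPM. Within sub-clusters 1 to 4 the log2 ratios were smaller, at 0.60, 0.76, 1.42 and 1.08 for Nr4a1. They lay between 0.57 and 0.99 for Nfkbid, 0.42 and 0.94 for Vegfa, and 0.35 and 0.97 for Gadd45b. Csrnp1, Rnf19b, Slc15a2, Areg, Ier3 and Cfap46 completed this side with Lyz2. The Lyz2 difference, 509 KO against 20 WT UMIs, rested on few cells, since 10 of the 60 KO cells with a UMI held 90.2% of its UMIs. Areg, at 167 KO and 33 WT UMIs, was gathered too, with 10 cells holding 62.3% in the KO and 66.7% in the WT library. Its log2 ratio was 2.36, against 0.12 to 1.29 within sub-clusters. With KO sub-clusters weighted to the WT make-up, 44 genes were 2-fold higher and 27 lower, and 38 of the 127 and 23 of the 76 were among them. The log2 ratio changed sign under that weighting for 1 of the 127 and 21 of the 76.

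On the lower side, Ifitm1, an interferon-induced membrane protein gene, stood at 5.10 CPM in the KO and 97.3 CPM in the WT library, a log2 ratio of -4.01. Its UMIs came from 13 KO cells and 253 WT cells, and 10 of the WT cells held 57.6% of those of the WT library. Mcpt8, a basophil protease gene, had 10 KO and 298 WT UMIs, carried by 3 and 64 cells, and 10 of the 64 held 71.1% of the WT UMIs. The metallothionein gene Mt2 stood at 5.83 and 38.5 CPM and the small heat shock protein gene Hspb1 had a log2 ratio of -1.91. Gzmd and Gzmg, granzyme genes on chromosome 14, and the proliferation genes Birc5, Ube2c, Ccnb2 and Hist1h2ap were also among the 12 lowest, with Zbtb32 and Filip1.

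**Figure D1:**
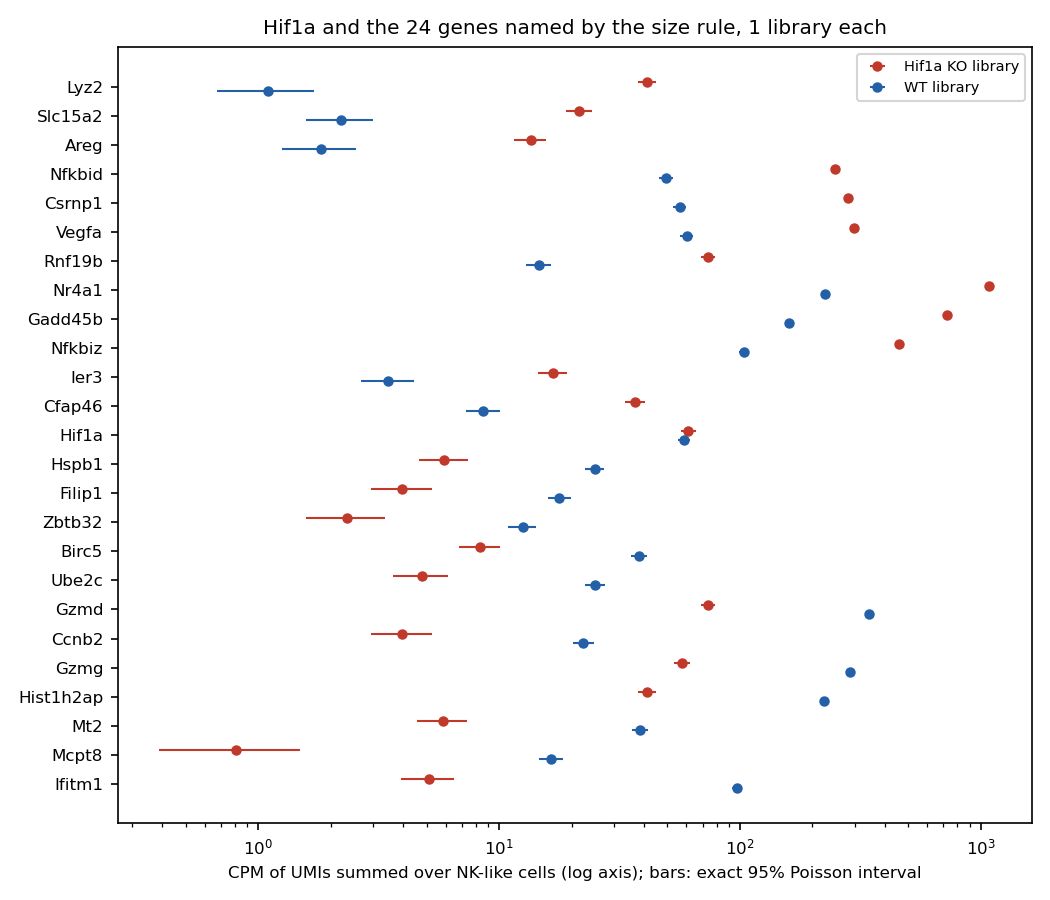
CPM of UMIs summed over NK-like cells on a log axis, with exact 95% Poisson intervals, for Hif1a and the 24 genes named by the size rule, in the KO library (red) and the WT library (blue). Hif1a stands at 61.0 and 58.7 CPM, while Nr4a1 stands at 1080 and 226 CPM and Ifitm1 at 5.10 and 97.3 CPM.

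Inflammatory and early-response genes were higher in the KO library. Of 21 measured NF-kB pathway and target genes, 13 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 0.70 (percentile 100 of matched random lists). Icam1 stood at 376 and 127 CPM and Tnfaip3, an inhibitor of NF-kB signalling, at 921 and 347 CPM. Within sub-clusters their log2 ratios ran from -0.066 to 0.39 and from 0.14 to 0.63. The immediate early list had a median of 0.90 (percentile 100), with 10 of 17 members at least 1.5-fold higher and 2 at least 1.5-fold lower. Btg2 stood at 1265 and 459 CPM. Fos and Fosb went the other way, at log2 ratios of -0.83 and -0.63, and were singled out after their values were seen, as was Jun at -0.34. Within sub-clusters the NF-kB median was smaller, from 0.040 to 0.29, and it was called apart only in sub-cluster 3, at percentile 99.6. The immediate early median was 0.42 and 0.24 in sub-clusters 1 and 2 (percentile 100 in both), but -0.056 and -0.0049 in sub-clusters 3 and 4, within the random range. The T-like cells, which lie outside the NK-like class, had an NF-kB median of 0.84 (percentile 100) and an immediate early median of 0.69 (percentile 100), and the unnamed Tmem176b cluster had -0.078 (percentile 18.0). The immediate early median of that cluster was 0.16, just inside the random range. Its members went both ways there, 4 at least 1.5-fold higher and 4 lower, with Nr4a1 at a log2 ratio of 1.21 (0.94 to 1.48) and Nr4a3 at 0.022 (-0.81 to 0.84).

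Cytokine genes and cytokine signalling lists were higher too. The cytokine and chemokine list had a median of 0.63 (percentile 100), with 7 of 13 members at least 1.5-fold higher. Within sub-clusters it was 0.24, 0.27, -0.026 and -0.0042 in numbers 1 to 4 and was called apart only in number 2, at percentile 99.5, and with KO sub-clusters weighted to the WT make-up it was 0.25. The chemokine gene Ccl4 stood at 3933 CPM in the KO and 1676 CPM in the WT library, and Ifng, encoding interferon gamma, at 723 and 340 CPM (log2 ratio 1.08, 1.04 to 1.13). Ifng did not go 1 way within sub-clusters, with log2 ratios of 0.55 in sub-cluster 2 and -0.038 in sub-cluster 3. IL-2 and IL-15 receptor signalling had a median of 0.47 (percentile 100), led by Pim1 at 2024 and 885 CPM. Within sub-clusters 1 to 4 the list had 0.15, 0.28, 0.35 and 0.12, called apart in numbers 2 and 3 only, and Pim1 had log2 ratios of 0.15, 0.24, 0.36 and 0.27. IL-12 and IL-18 receptor signalling had 0.28 (percentile 99.7), with Stat4 at 293 and 148 CPM. The TGF-beta response list had 0.59 (percentile 100), with Pmepa1 at 31.4 and 7.94 CPM, Tgif1 at 342 and 122 CPM, and 8 of 14 members at least 1.5-fold higher. Outside the NK-like class, the cytokine and chemokine median was -0.57 in T-like cells and -0.80 in the unnamed Tmem176b cluster, both below the random range. In the same order, the TGF-beta median was 0.98 and 0.35, over 5 genes each. Both values were those of Junb, which is also a member of the immediate early list. At least 1.5-fold higher were 3 of the 5 genes in T-like cells and 1 in the cluster, and 0 were as much lower. The IL-12 and IL-18 median was 0.66 and 0.26. The TGF-beta median and the IL-12 and IL-18 median lay above the random range in both groups. The IL-2 and IL-15 median lay within it, at 0.14 and 0.19. The activation list had 0.29 (percentile 99.5) over members that went both ways. Cd83 stood at 63.6 and 25.3 CPM, whereas Il2ra, the IL-2 receptor alpha chain gene, stood at 6.07 and 14.2 CPM and Ly6a at 12.5 and 28.1 CPM. With KO sub-clusters weighted to the WT make-up, the activation and the IL-12 and IL-18 lists lay within the random range, at 0.0094 and 0.086, and Ly6a changed sign to 0.087. That sign rests on sub-cluster 5, which held 18 KO and 130 WT cells. Ly6a was -0.23 in that weighting with the sub-cluster left out of both libraries. Il2ra had a log2 ratio of 0.090 without cells carrying S and G2M genes.

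**Figure D2:**
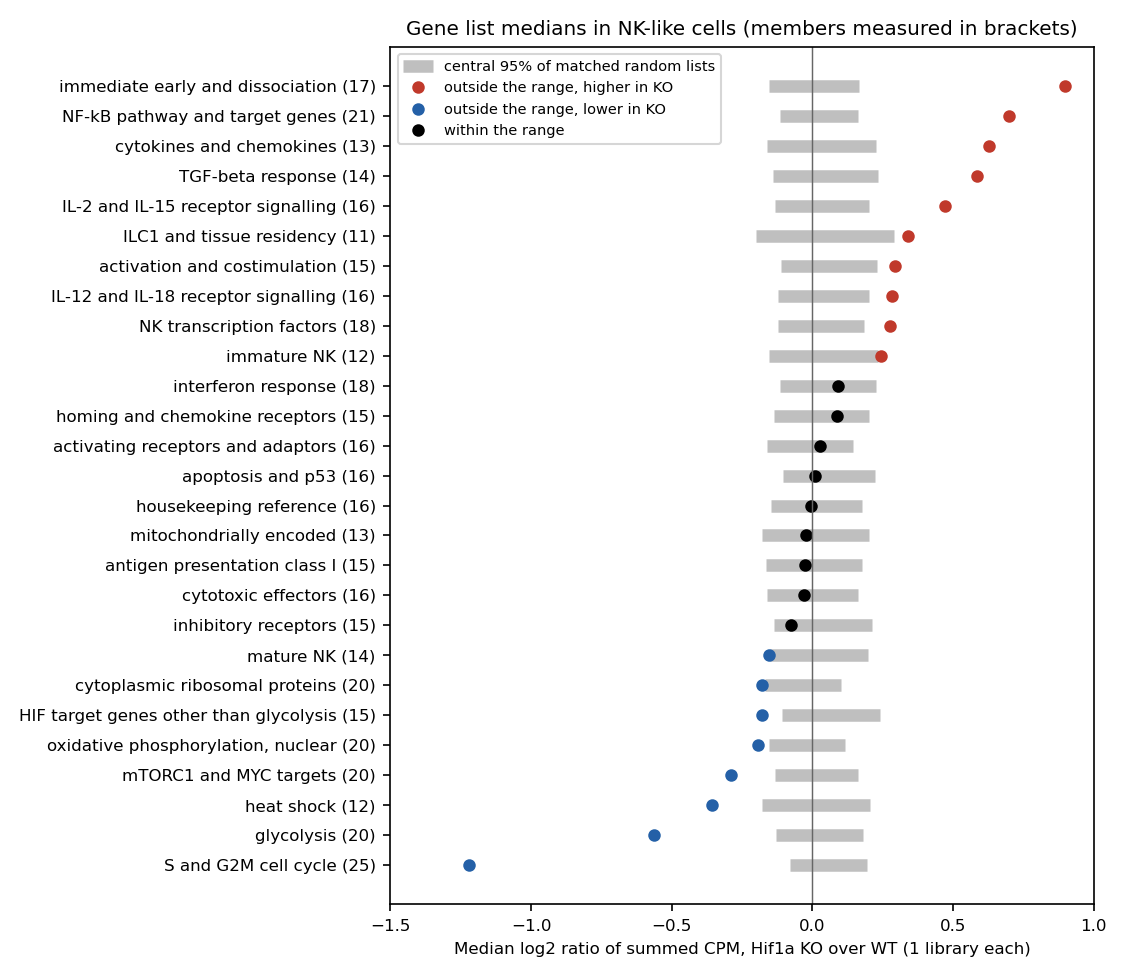
Median log2 ratio of summed CPM, KO over WT, in NK-like cells for 27 gene lists (points), with the central 95% of medians of 10000 expression-matched random lists (grey bars) and the number of measured members in brackets. The immediate early list lies highest at 0.90 and the S and G2M list lowest at -1.22.

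Glycolysis genes were lower in the KO library. The median over 20 members was -0.56 (percentile 0), with 9 at least 1.5-fold lower and 1 at least 1.5-fold higher. Pgk1 (chromosome X, 106187100 to 106203699), encoding phosphoglycerate kinase, stood at 61.0 CPM in the KO and 127 CPM in the WT library (log2 ratio -1.05, -1.18 to -0.94). Gapdh stood at 480 and 908 CPM and Tpi1, encoding triosephosphate isomerase, at 151 and 277 CPM. The glycolysis median was below 0 in each of the 4 sub-clusters compared, between -0.47 and -0.18, at percentile 0.06 or lower. Other HIF target genes went both ways, with a median of -0.18 (percentile 0.26) that lay within the random range without cells carrying S and G2M genes (-0.051) and with no count minimum for members (-0.047). It kept its call under 12 of 14 alternatives. Within sub-clusters 1 to 4 the median was 0.14, -0.39, -0.038 and -0.16, called lower only in number 2 (percentile 0). Ankrd37 stood at 2.43 and 10.8 CPM and Fam162a at 45.5 and 68.2 CPM, while Vegfa and Ier3 were higher in the KO library. Nuclear oxidative phosphorylation genes had a median of -0.19 (percentile 0.31), with none of 20 at least 1.5-fold apart. That median was within the random range without cells carrying S and G2M genes (-0.13) and with KO sub-clusters weighted to the WT make-up (-0.055). Mitochondrially encoded genes had -0.023 (percentile 53.8). The mTORC1 and MYC target list had -0.29 (percentile 0), with Psat1, a serine synthesis gene, at 11.3 and 23.3 CPM, and lost its call under the same pair of alternatives, at -0.043 and -0.055. Cytoplasmic ribosomal protein genes had -0.18 (percentile 1.44) and the housekeeping list -0.0064 (percentile 49.3).

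Cell cycle genes were lower in the KO library. The S and G2M list had a median of -1.22 (percentile 0), with 18 of 25 members at least 1.5-fold lower. Birc5 stood at 8.34 and 38.2 CPM and Ccna2 at 2.27 and 14.0 CPM. Sub-cluster 5, led by Hist1h2ap, Birc5 and Rrm2, held 18 KO and 130 WT cells and carried 16.1% of the list's UMIs in the KO and 47.8% in the WT library. Within sub-clusters the list did not go 1 way, with medians of 0.0052 (percentile 34.6), 0.33 (percentile 99.8), -0.18 (percentile 0.16) and -0.30 (percentile 0.285) in numbers 1 to 4. With KO sub-clusters weighted to the WT make-up the median was 0.20, which rests partly on the 18 KO cells of sub-cluster 5, and without that sub-cluster it was 0.10, within the random range. After thinning, at least 2 list genes were detected in 31.3% of KO NK-like cells (29.5% to 33.2%) and 35.0% of WT cells (33.3% to 36.7%). The same share was 23.8% (14.0% to 36.2%) and 30.8% (22.3% to 40.5%) in T-like cells. At least 3 genes were detected in 9.52% of KO and 14.2% of WT NK-like cells, and in 7.94% (2.63% to 17.6%) of KO and 6.54% (2.67% to 13.0%) of WT T-like cells.

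Cytotoxic effector genes did not move together. Their median was -0.030 (percentile 50.3) over 16 members, with 5 at least 1.5-fold lower, among them Gzmc, Gzmd, Gzme and Gzmf, and 1 at least 1.5-fold higher, Serpinb9 at 858 and 471 CPM, which was singled out after its values were seen. Within sub-cluster 1 the list was called lower, at -0.25 (percentile 0.040), and in sub-clusters 2 to 4 it lay within the random range. Gzmc (chromosome 14, 56231441 to 56234656) stood at 236 CPM in the KO and 996 CPM in the WT library (log2 ratio -2.07, -2.13 to -2.02), and Gzme at 24.6 and 151 CPM. Gzmc to Gzmg summed to 508 and 2112 CPM, and sub-cluster 5 carried 71.6% of those UMIs in the KO and 85.8% in the WT library. In WT cells, 10 cells held 65.2%, 77.0% and 69.1% of the UMIs of Gzmd, Gzmf and Gzmg, and in KO cells 10 held 89.2%, 85.4% and 91.2%. With KO sub-clusters weighted to the WT make-up, Gzmd, Gzmf and Gzmg no longer were lower in the KO library, at log2 ratios of 0.10, 0.69 and 0.012. That weighting rests on 18 KO cells of sub-cluster 5, and without that sub-cluster the ratios were -1.68, -0.27 and -1.89.

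Maturation and identity lists went both ways. The mature NK list had a median of -0.15 (percentile 2.15), with Klrg1 at 121 and 197 CPM and Lgals1 at 1987 and 3056 CPM, but Cma1 at 455 and 237 CPM. The immature NK list had 0.24 (percentile 97.8), with Emb at 352 and 238 CPM (log2 ratio -0.036 under the WT make-up) and Thy1 at 150 and 224 CPM. Sub-clusters were called in both directions, for the mature list lower in numbers 1 and 2 (-0.17 and -0.15) and higher in number 4 (0.18), and for the immature list higher in number 1 (0.53) and lower in number 2 (-0.17). Neither list was apart from random lists with KO sub-clusters weighted to the WT make-up, at 0.040 and -0.045. The ILC1 and tissue residency list had 0.34 (percentile 98.9), with Il21r at 94.7 and 41.0 CPM and Rgs2 at 641 and 439 CPM. Over 5 or 6 measured members it was 0.47, 0.14 and 0.039 in sub-clusters 1 to 3, called apart only in number 1. Too few members were measured in number 4. Rgs2 had log2 ratios of 0.69, 0.068, -0.018 and -0.055 in numbers 1 to 4. NK transcription factors had 0.28 (percentile 99.7), with Nfil3 at 105 and 65.6 CPM and Tbx21, encoding T-bet, at 118 and 77.6 CPM, but lay within the random range under the WT make-up, at 0.10 with sub-cluster 5 and 0.095 without it. Inhibitory receptors had -0.077 (percentile 12.2) over sub-cluster medians that went both ways, called lower in sub-clusters 1 and 3 (-0.27 and -0.12) and higher in sub-cluster 2 (0.23), although Havcr2, encoding TIM-3, stood at 7.20 and 19.7 CPM. The Havcr2 log2 ratio was -0.22 under the WT make-up, 0.54 under that weighting without sub-cluster 5, and -0.37 without cells carrying S and G2M genes. Activating receptors had 0.029 (percentile 78.2), homing receptors 0.086 (percentile 80.6), interferon response genes 0.090 (percentile 68.4), class I antigen presentation -0.027 (percentile 50.8), and apoptosis and p53 genes 0.010 (percentile 33.8). Within these, Cxcr4 stood at 149 and 61.4 CPM, Isg15 at 55.4 and 23.8 CPM, and the pro-apoptotic gene Bcl2l11 at 740 and 277 CPM.

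Heat shock genes were lower in the KO library, with a median of -0.36 (percentile 0) and 3 of 12 members at least 1.5-fold lower. Hspa1a stood at 356 and 942 CPM and Hspa1b, its near-identical neighbour, at 58.9 and 120 CPM. Dnaja1 went the other way, at 551 and 361 CPM. The heat shock median was also below 0 in the T-like cells, at -0.34 (percentile 0.385), and in the unnamed Tmem176b cluster, at -0.41 (percentile 0). Within NK-like sub-clusters 1 to 4 it was -0.064, 0.28, -0.54 and -0.15, called lower only in number 3 and higher only in number 2.

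**Figure D3:**
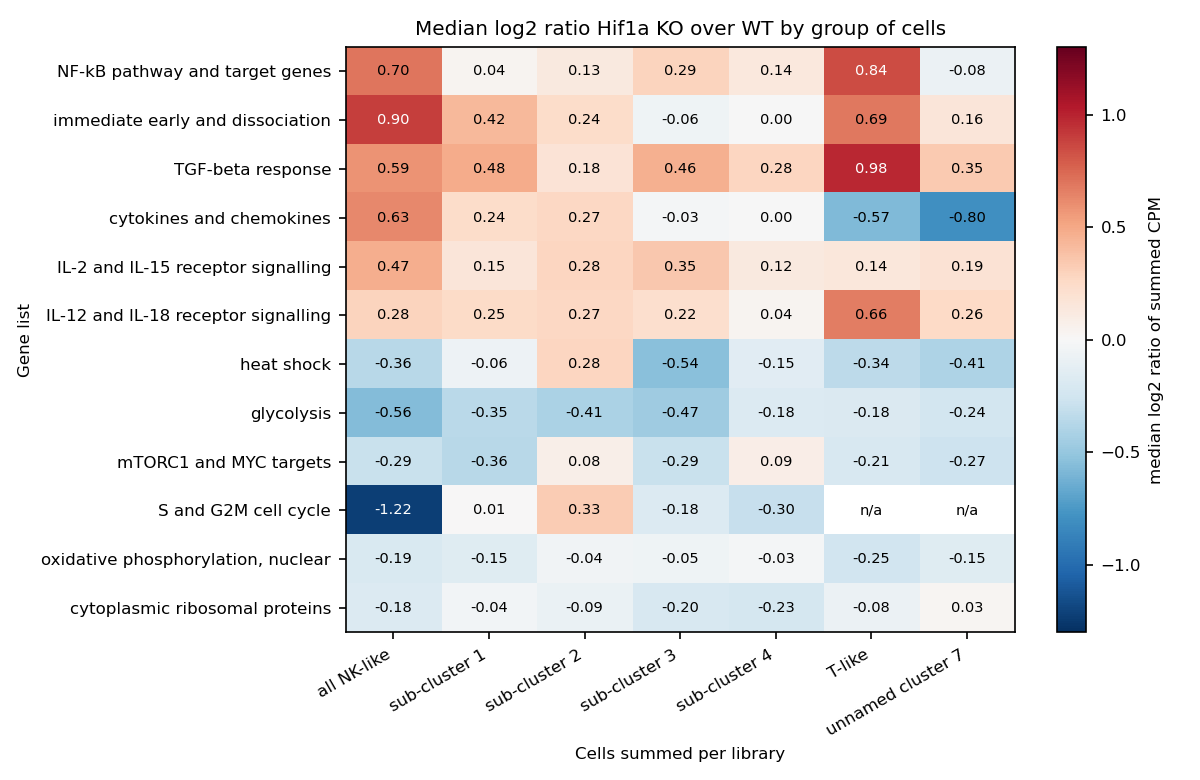
Median log2 ratio of summed CPM, KO over WT, for 12 gene lists (rows) in all NK-like cells, in the 4 NK-like sub-clusters compared, in T-like cells and in unnamed cluster 7 (columns), where n/a marks fewer than 5 measured members. The NF-kB median is 0.70 in all NK-like cells, 0.040 to 0.29 in the sub-clusters and 0.84 in T-like cells, whereas the glycolysis median is below 0 in every column.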

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

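In this part, the tests on heat shock genes, nuclear RNA, granzyme copies, abundant transcripts and the S and G2M list under the raised UMI floor were chosen only after the results they bear on had been seen. Signal appeared in cells that the comparisons leave out. T-like cells made up 2.25% of the KO and 3.04% of the WT library although CD3ε-positive cells had been sorted out. Of the 177 T-like cells, 66.7% carried a Cd3e UMI, 67.8% a UMI of Klrb1c, which encodes NK1.1, and 31.1% a Ncr1 UMI. Unnamed cluster 7, in which 80.5% of cells carried Tmem176b and 85.0% Ncr1, held 85 KO and 115 WT cells. Unnamed cluster 10, led by Gm525, Insl5 and Mt1, held 6 KO and 6 WT cells. Among barcodes left out, 34 KO and 17 WT barcodes had at least 10% hemoglobin UMIs.

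The first pattern was the higher NF-kB and immediate early lists in the KO library. The lower UMI floor of the KO library is argued against by an NF-kB median of 0.69 with KO cells held to the WT floor. A stronger dissociation stress in the KO preparation stays open, since the heat shock median was -0.36 in all NK-like cells and -0.41 in unnamed cluster 7, but 0.28 in sub-cluster 2, where the immediate early median was 0.24. Sub-cluster composition is open too, with a lowest sub-cluster median of 0.040 for NF-kB and -0.056 for the immediate early list. These medians cannot decide it, since sub-cluster 1 was itself led by Nr4a1, Nfkbiz and Nfkbid. Splitting by such clusters lowers the difference also where the same cells changed state. A higher nuclear RNA share in the KO library also stays open, with a median of 0.51 over Malat1, Neat1, Xist, Tsix and Kcnq1ot1. A difference of tumor, mouse or preparation predicted the same shift in T-like cells and found it, at 0.84 over 13 NF-kB genes in 69 KO and 108 WT cells, and a later moment of 1 handling response predicted lower Fos, Fosb and Jun there and found a mean log2 ratio of -1.51. Fos, Fosb and Jun had been picked from their values in NK-like cells, before those in T-like cells were seen. The shift may owe something to causes other than Hif1a in NK cells, but the T-like values cannot separate these from the genotype. Of the T-like cells, 67.8% carried a Klrb1c UMI and 31.1% a Ncr1 UMI, so they shared genes with the NK-like class. Doublets had also been kept. Unnamed cluster 7 gave no clear answer for the lists, with an NF-kB median of -0.078 and an immediate early median of 0.16. Icam1 and Nr4a3 stood there at 0.031 and 0.022. Of the 12 highest genes of NK-like cells, those with values in cluster 7 were all higher in the KO library. These were Areg, Rnf19b, Csrnp1, Nfkbid, Nr4a1, Vegfa, Nfkbiz and Gadd45b. Their log2 ratios ran from 0.77 to 2.78, Nfkbid and Nr4a1 at 1.42 and 1.21, with each interval above 0. They had been chosen for their ratios in NK-like cells of the same libraries. Other named genes that were higher in KO NK-like cells went both ways in cluster 7. Btg2 and Tgif1 were higher there, at 0.89 and 0.83. Cd83, Csf2, Isg15 and Cxcl10 were lower, at -0.71, -1.04, -1.14 and -1.66, with each interval below 0. Whether cells outside the NK-like class carry the deletion is not known, and the genotype remains open and untested.

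The second pattern was the lower S and G2M list and Gzmc to Gzmg in the KO library. The UMI floor is argued against by an S and G2M median of -1.21 with KO cells held to the WT floor; the cycling share under that floor, with a WT over KO ratio of 1.12, decided nothing because thinning had already removed those cells. Without cells carrying S and G2M genes the summed log2 ratio of Gzmc to Gzmg was -1.21 (-1.31 to -1.12). That argues against fewer cycling cells as the whole cause, but the interval does not cover how UMIs spread over cells. In all NK-like cells, 10 cells held 66.0% of KO and 49.1% of WT Gzmc UMIs. Reads moved between granzyme copies are argued against by a log2 ratio of -0.58 (-0.60 to -0.56) for the sum of Gzmb to Gzmg, which such moves would leave unchanged. A difference of tumor, mouse or preparation cannot be told apart from the genotype with 1 library of each, and the small number of KO cells in sub-cluster 5, 18, limits what the granzyme values can show. Outside the NK-like class, Gzmc had a log2 ratio of -1.05 (-1.20 to -0.91) in unnamed cluster 7. In T-like cells it had -0.62 (-1.41 to 0.099). Gzmd had -0.67 (-1.62 to 0.18) in cluster 7.

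The third pattern was the lower glycolysis list in the KO library. A general loss of abundant transcripts is argued against by the medians of expression-matched random lists, whose lower 2.5% limit was -0.13 against -0.56 for glycolysis, and sub-cluster composition alone by the highest sub-cluster median of -0.18 at percentile 0.06. Without cells carrying S and G2M genes the median was -0.32, so fewer cycling cells could account for a part. That filter used unthinned counts and took out 47.9% of KO and 59.0% of WT NK-like cells. It therefore depends on depth, and the smaller median cannot be credited to cycling alone. A difference that also reaches other cells stays open, since the T-like median was -0.18 (percentile 10.4) and that of unnamed cluster 7 -0.24 (percentile 1.45), over 10 genes each. Loss of Hif1a, which is known to drive glycolysis genes, is a candidate explanation that 1 library per genotype leaves untested.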

How the results depend on the processing

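Chosen after seeing the data were holding KO cells to the WT library's lowest barcode (2364 UMIs, which left out 339 KO NK-like cells), leaving out the highest 3% of Scrublet scores, leaving out hemoglobin-rich cells, and weighting without sub-clusters under 20 cells. The alternative for normalized files was not run, since the files hold counts, and no paired analysis was possible because there is 1 library per genotype. Of 378 list medians under alternatives, 346 kept their call. The NF-kB (0.23 to 0.72), immediate early (0.22 to 0.90), TGF-beta (0.32 to 0.66), cytokine (0.25 to 0.79), IL-2 and IL-15 (0.23 to 0.47), ILC1 (0.26 to 0.59), glycolysis (-0.64 to -0.32) and heat shock (-0.43 to -0.13) lists kept it under all 14. For named genes, 1096 of 1560 ratios stayed within the counting interval, 447 left it and 17 changed sign. Unless the setting itself names it, the cause was not tested. Sparse genes, such as Mcpt8 with 10 KO UMIs, are limited by depth.

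Genes at least 2-fold higher numbered 84 without cycling cells, 44 with KO sub-clusters weighted to the WT make-up, 42 with that weighting without sub-cluster 5, 243 with no count minimum, 68 at 1000 UMIs and 63 with a prior of 10 CPM. Genes at least 2-fold lower numbered 23, 27, 26, 158, 25 and 31 in that order, and 134 at 50 UMIs. Without cycling cells 5326 genes reached the minimum, against 7997, and with the minimum not applied anew 105 of the 127 and 33 of the 76 stayed 2-fold apart. Cycling cells here had at least 2 S and G2M genes before thinning. They were 1391 KO and 1964 WT NK-like cells, and the cut depends on depth.

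Without cycling cells the list medians that lost their call were HIF targets (-0.051), oxidative phosphorylation (-0.13), immature NK (0.086), S and G2M (0.00045, where the filter itself removes the list's UMIs) and mTORC1 and MYC (-0.043), while inhibitory receptors (-0.18) and apoptosis (0.26) gained one. With KO sub-clusters weighted to the WT make-up, oxidative phosphorylation (-0.055), activation (0.0094), IL-12 and IL-18 (0.086), mature NK (0.040), immature NK (-0.045), NK transcription factors (0.10) and mTORC1 and MYC (-0.055) lost it, cytotoxic effectors gained it (0.098) and S and G2M changed sign (0.20). With that weighting without sub-cluster 5, medians without a call were oxidative phosphorylation (-0.056), activation (-0.015), IL-12 and IL-18 (0.16), mature NK (0.061), immature NK (-0.027), NK transcription factors (0.095), S and G2M (0.10) and mTORC1 and MYC (-0.042). Calls also ended for mature NK under median-of-ratios scaling (-0.23) and with members of at least 200 UMIs (-0.15), for immature NK with all barcodes (0.19), equal cell weights (0.19) and members of at least 200 UMIs (0.20), for HIF targets (-0.047) and activation (0.16) with no member minimum, and for ribosomal proteins at the WT floor (-0.15).

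Single genes changed sign with KO sub-clusters weighted to the WT make-up: Cxcl10 (-0.041), Ccr7 (-0.33), Emb (-0.036), Srm (0.073), Ly6a (0.087), Gzmf (0.69), Gzmd (0.10) and Gzmg (0.012). Without sub-cluster 5 in that weighting they were Ccr7 (-0.34), Emb (-0.11), Srm (0.13), Klra5 (0.10), Il2ra (0.10), Havcr2 (0.54) and Ccnb2 (0.12). Without cycling cells they were Tmem176b (-0.25) and Il2ra (0.090).

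The NK-like share of the KO library was 93.4% at resolution 1.6, 93.6% with all barcodes and 93.7% clustered alone, and that of the WT library 87.3% at resolution 1.6. At that resolution the rule named a cluster of 38 KO and 217 WT cells dendritic, from H2-Aa, H2-Eb1, Cd74 and H2-Ab1. On average 77.7% of its cells carried an NK marker, against 72.0% to 84.4% in clusters named NK. The cycling share was 9.52% KO and 14.2% WT at 3 genes, 47.9% and 59.0% without thinning, and 39.5% and 43.5% at 3100 UMIs. The share with a Hif1a UMI was 20.6% KO and 24.7% WT without thinning, and 16.2% and 15.5% at 3100 UMIs.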

Other observations

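The cytokine and chemokine median of the small unnamed Tmem176b cluster was -0.80 (percentile 0, 10 genes), against 0.63 in NK-like cells, and that of T-like cells was -0.57 (percentile 0.01, 7 genes). Not all members turned, since Ifng was higher in the KO library in both, at log2 ratios of 0.64 and 0.71, as was Ccl4 in the Tmem176b cluster, at 0.47. The difference between these cells and the NK-like class was not tested. Rora, Il7r and Cxcr6 set the cluster apart, at 326, 227 and 116 CPM against 23.4, 11.4 and 1.28 CPM in NK-like cells. The 12 cells of cluster 10 had a median of 15229.5 UMIs. Cd3g was found in 11 of them and Dntt, a lymphoid precursor polymerase gene, in 8, while Ncr1 was found in 2. Their identity was not assigned.

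Hemoglobin RNA was found in NK-like and T-like cells. After thinning, a Hbb-bs UMI was found in 36.6% of KO and 19.7% of WT NK-like cells, and in 44.4% and 21.5% of T-like cells. Summed over NK-like cells, Hbb-bs stood at 181 CPM in the KO and 361 CPM in the WT library, but at 181 and 88.1 CPM without the 3 WT cells that had at least 10% hemoglobin UMIs. Its source was not tested, and Hbb-bs was chosen after its values were seen. Malat1 stood at 28867 CPM in KO and 20270 CPM in WT NK-like cells, and the median share of ribosomal protein UMIs was 23.7% and 26.0%.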
